A study of Homo sapiens with 4 samples.

How the data were processed

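RNA of UMUC3 and SW780 cells, with SCD1 knocked down (shSCD1) or labelled shNT, was sequenced from TruSeq libraries on an Illumina NovaSeq instrument, per the labels' protocols, with 1 library in each of the 4 groups. The genome build was hg38, per the submitters' processing notes. The aligner, the read counter, the annotation release, whether strand was used and how genes were chosen for each table are not given in the sources used here. The labels do not say from how many cultures or hairpins each library came.

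The authors deposited 1 table per cell line, which per the file headers holds a GFOLD value at a setting of 0.01, an empirical FDR, a log2 fold change and 2 columns headed RPKM. GFOLD is a log2 fold change shrunk towards 0 by counting error. The deposited log2 fold change is the second library over the first with the authors' own scaling, which differs from the plain ratio of the 2 columns by a median of −0.08 in UMUC3 and 0.005 in SW780. The deposited empirical FDR is 1 for every gene and was not used. Although headed RPKM, the deposited signal in each column is a read count scaled to the same total in every library, with no gene length in it. Among low values (up to 20 reads), 100% were within 0.1 reads of a whole multiple of 1 step per column, and over all values above 0 at least 99.9% were, so whole reads were recovered by dividing by that step. The step was worth 1 read, 2.19 units in UMUC3 shNT, 1.54 in UMUC3 shSCD1, 1.47 in SW780 shNT and 1.96 in SW780 shSCD1.

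The headers name the libraries first and second and not by group. The second was taken as shSCD1 because the fold change tables carry that name and give second over first. In UMUC3 the labels also number shNT as library 1 and shSCD1 as library 2; for SW780 the numbering gives only their order, so the reading rests on the table's name. SCD was not used for this choice, but its lower value in the second library of both tables is the only check of it.

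The design written before the data were examined named RPKM, or CPM for counts. As the columns were scaled counts, CPM from the recovered reads was used. Totals were 22818368 reads for UMUC3 shNT, 32540576 for UMUC3 shSCD1, 34087871 for SW780 shNT and 25549737 for SW780 shSCD1, over the genes of each table. A gene with 0 reads may have had up to 3 (0.131, 0.0922, 0.0880 and 0.117 CPM, in the same order). There were 30148 genes for UMUC3 and 17752 for SW780, the latter nearly all protein-coding among those measured (99.5%), and 15415 are in both. Gene names came from the tables or, where these gave none, from a table of Ensembl gene names, which matched 99.4% and 99.9% of the entries.

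Log2 ratios used CPM plus 1. Genes with at least 1 CPM in either library were kept, 14063 in UMUC3 and 12880 in SW780, and a log2 ratio of at least 1 in size (2-fold) was the size rule. Fold intervals are exact Clopper-Pearson 95% intervals of the shSCD1 share of a gene's reads, turned into folds. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Folds against 0 reads are lower bounds at a floor of 3 reads per library.

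Before the data were examined, 31 gene lists with 836 genes were written from textbook knowledge of lipid metabolism, stress responses, the cell cycle, immunity, epithelial, mesenchymal, urothelial and other cell types, and signalling. Each list's median ratio is given as its percentile among 10000 random lists with as many genes in each of 20 expression bins, for lists with at least 3 measured genes. This describes these libraries and is no test. Of 30 lists with a value, 2 lay above percentile 97.5 and 14 below percentile 2.5 in UMUC3, and 9 and 4 in SW780. By construction of the percentiles 0.75 would be beyond each if the lists were drawn at random. Genes of a list may move together and some lists share genes, so the excess over 0.75 is no measure against chance.

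Genes were named by a rule fixed at the same time: SCD; the 10 highest and 10 lowest ratios per line among genes with at least 5 CPM, leaving out names of clones, small RNAs, antisense and long non-coding genes; up to 10 genes each that were higher, lower or opposite in both lines, by the smaller ratio; up to 4 genes per list, and more where 5 or fewer of a list passed the size rule; and lipid genes past the size rule. A few genes outside this rule were chosen after their values were seen (HSPA5, MX1, IFI27, FN1, CDH2, MMP2, COL3A1, LUM, FOXA1, KRT19, FASN, PECAM1, RN7SL1, RN7SL2 and RN7SL4P). Some genes that the rule takes are not reported here. Positions, gene types and the share of exonic bases in exons of another gene on either strand came from GENCODE 29, and so did GC content and transcript length.

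The computations were tested on simulated data first. With the real totals and Poisson counts, 100% of reads were recovered exactly. In UMUC3 54 of 63 genes changed 3-fold passed the size rule and in SW780 58 of 64; of genes changed 1.5-fold, 0 of 68 and 0 of 69 did, and of 13605 and 12585 unchanged genes none did. This simulation holds no variation between cultures. Of 300 random lists, 6.33% and 5.00% fell beyond the 2 percentiles.

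The alternatives fixed beforehand were a pseudocount of 0.1, centring on the median or on a mean with 30% trimmed at each end, no filter, a filter at 5 CPM, a log2 ratio of at least 0.5 and the authors' values. Added after seeing the data were the deposited scale, the removal of genes that share exons or are not in GENCODE 29, the removal of the trend with GC content and length (medians of 20 bins each), list medians over genes measured in both lines alone, with random lists from the same genes, and count tests. The count tests fitted the reads of all 4 libraries with cell line as a block and knockdown as the effect, which leaves 1 residual degree of freedom, over 13554 genes, with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 in R 4.3.3. In a simulation of that design with 13638 genes, edgeR called 22 of 68 genes changed 2-fold, 61 of 63 changed 4-fold and 69 of 69 changed 8-fold, and 7 of 13438 unchanged ones; DESeq2 called 19, 55 and 64, and 9 unchanged ones. That simulation gave every gene the same dispersion and gave changed genes the same fold in both lines. It therefore does not show what the tests would find where dispersion differs between genes or the lines respond differently. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.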

Results

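Gene expression was measured by RNA sequencing in 2 human bladder cancer cell lines, UMUC3 and SW780. In each line, cells in which SCD1 had been knocked down by lentivirus (labelled shSCD1) were set beside cells labelled shNT, whose genotype is given as WT. SCD1 is the stearoyl-CoA desaturase that makes monounsaturated fatty acids, and its gene symbol is SCD. The 4 groups held 1 library each, so there was no replicate check, no test was made within a line, and "higher" and "lower" describe these libraries alone. Reads were totalled over the genes deposited for each line, so the totals are not whole library sizes. They were 22818368 (shNT) and 32540576 (shSCD1) in UMUC3, and 34087871 (shNT) and 25549737 (shSCD1) in SW780. Ratios are log2((shSCD1 CPM + 1)/(shNT CPM + 1)), where CPM is a gene's read count scaled by the total of its library, and the added 1 CPM understates the change of weakly expressed genes. A gene passed the size rule with a log2 ratio of at least 1 in either direction and at least 1 CPM in either library. Folds are ratios of CPM without the added 1, and their 95% intervals cover counting error only.

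The deposited tables call their libraries only the first and the second. The second was read as shSCD1 and the first as shNT, because each fold change table carries the name shSCD1 and its ratios are second over first. The headers do not state this, and every direction given for a line would turn round if the columns of its table stood in the other order.

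The first question was whether the targeted gene was lower where it had been knocked down. SCD (ENSG00000099194) lies on chromosome 10 from 100347124 to 100364834, on the plus strand (GRCh38, GENCODE 29), and shares 0% of its exonic bases with another gene. In UMUC3 it stood at 264 CPM in the shNT library and 59.6 CPM in the shSCD1 library, a log2 ratio of −2.13 and a 4.44-fold lower level (95% interval 4.22 to 4.67). In SW780 it stood at 592 CPM and 92.1 CPM, a log2 ratio of −2.67 and a 6.43-fold lower level (6.16 to 6.71). The authors' deposited tables give SCD a log2 fold change of −2.23 in UMUC3 and −2.68 in SW780.

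The second question was what differed in UMUC3 beside SCD. In UMUC3 the median log2 ratio was below those of random lists for interferon response, MHC class I and glycolysis genes (−0.55, −0.60 and −0.38), of which 8 of 24, 1 of 19 and 2 of 30 passed the size rule. It was above them for DNA replication genes and transcripts of the mitochondrial genome (0.57 and 0.67), of which 3 of 35 and 1 of 13 passed. HAS2, which makes hyaluronan, was 36.0-fold lower (23.1 to 59.5). ANKRD1, a target of the YAP coactivator, was 15.8-fold lower (13.5 to 18.7). INHBA, which encodes the activin A subunit, had 282 reads in the shNT library and 0 in the shSCD1 library, at least 134-fold lower against a floor of 3 reads. Of 14063 genes with at least 1 CPM, 347 were higher and 306 lower by the size rule. With ratios centred on their median the counts were 318 and 321, so which side held more genes depended on the scaling.

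Among other genes at the low end, CPA4, a secreted carboxypeptidase, was 16.2-fold lower (13.4 to 19.7), ARHGDIB 23.3-fold lower (15.5 to 36.4), and ABLIM1, an actin-binding protein, 14.2-fold lower (11.1 to 18.4). THBS1, which encodes thrombospondin 1, was 12.3-fold lower (8.73 to 17.8), and the zinc finger gene ZNF888 17.8-fold lower (11.3 to 29.6). At the high end, CYFIP2, a subunit of the WAVE actin regulatory complex, was 15.5-fold higher (8.75 to 30.5) and NOS2, the inducible nitric oxide synthase, 13.6-fold higher (7.24 to 28.8). KIF5C, a kinesin heavy chain, was 9.01-fold higher (6.04 to 14.0), PID1 6.86-fold (4.88 to 9.90), and SLAIN1 5.66-fold (4.28 to 7.61). DDR2, a collagen receptor, went from 16.1 to 76.1 CPM, 4.72-fold higher (4.23 to 5.28), and NTSR1, a neurotensin receptor, from 7.80 to 37.6 CPM, 4.82-fold higher (4.11 to 5.67).

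In the interferon response list, 18 of 24 measured members were below 0 and 8 were lower by the size rule, with none higher. The list's median was −0.55, at percentile 0 of 10000 random lists of like expression. IFIT2 was 16.3-fold lower (9.43 to 30.5), SAMD9L 4.49-fold (3.51 to 5.80), and IFITM2 8.12-fold (4.47 to 16.0). Of 19 genes of MHC class I antigen presentation, 17 were below 0 and the median was −0.60 at percentile 0, although PSMB9, an immunoproteasome subunit, was alone in passing the size rule (2.56-fold lower, 1.89 to 3.49). In the list of NF-kB targets and cytokines the median was −0.26 at percentile 0.3. CCL2 was 5.32-fold lower (4.62 to 6.14) and CXCL8 3.23-fold lower (2.78 to 3.76), both chemokines, and IL32 and CSF1 also passed the rule as lower.

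Of 25 mesenchymal genes, 19 were below 0 and 5 were lower by the size rule (COL5A1, TGFBI, SPARC, SNAI2 and WNT5A), with a median of −0.60 at percentile 0. SPARC, a matrix glycoprotein, went from 232 to 99.5 CPM. Of 20 YAP and TEAD targets, 15 were below 0, the median was −0.28 at percentile 0.05, and CCN1 went from 1575 to 521 CPM, 3.02-fold lower (2.97 to 3.08). The 6 measured basal and squamous genes had a median of −0.55 at percentile 0.13, and none passed the size rule. Of 30 genes of hypoxia and glycolysis, 24 were below 0 with a median of −0.38 at percentile 0; the glucose transporter gene SLC2A1 was 2.37-fold lower (2.22 to 2.52) and BNIP3 2.40-fold lower (2.28 to 2.52). In the list of ER chaperones, 19 of 24 were below 0 and the median was −0.20 at percentile 0.2, with DNAJB9 at a log2 ratio of −0.94 and HSPA5 at −0.48.

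Of 35 DNA replication and G1/S genes, 32 were above 0 and the median was 0.57 at percentile 100. CCNE2, which encodes cyclin E2, was 3.07-fold higher (2.70 to 3.50), CLSPN 2.53-fold (2.32 to 2.77), and E2F2 2.13-fold (1.86 to 2.45); these 3 passed the size rule. The 37 genes of mitosis and G2/M had a median of −0.10 at percentile 6.16, or percentile 1.02 with the trend with GC content and length removed. All 13 transcripts of the mitochondrial genome were above 0, with a median of 0.67 at percentile 100, MT-ATP8 alone passed the size rule, and their share of reads went from 4.23% to 6.02%.

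The lipid lists of UMUC3 held few genes past the size rule. Besides SCD, ELOVL7, a fatty acid elongase, passed the size rule among 20 genes of fatty acid synthesis and desaturation (2.13-fold higher, 1.82 to 2.49), and the list's median was 0.05 at percentile 67.1. None of the 24 cholesterol genes passed it, 17 were above 0, and the median was 0.15 at percentile 96.4, with HMGCS1 at 0.74. Among 26 genes of fatty acid uptake and oxidation, with a median of −0.16 at percentile 1.18 (3.09 with the trend with GC content and length removed), SLC27A2, a fatty acid transporter, had 0 reads in the shNT library and 48 in the shSCD1 library, and ACSL5, an acyl-CoA synthetase, 35 and 4.

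The counts in UMUC3 rest on the choice of rule and on the scaling. The authors' deposited table gives a GFOLD value above 0 to 3826 genes and below 0 to 6042. That is a share of 38.8% higher against 53.1% by the size rule, which also asks for a size. The authors' log2 fold change also has its own scaling, which differs from the plain ratio of the deposited columns by a median of −0.08. How far each accounts for the difference in shares was not tested. With a GFOLD of at least 1 in size, the authors' deposited table has 210 genes higher and 357 lower. Read-through and duplicated gene models stood among the largest ratios and are uncertain, because at least 50% of their exonic bases lie in exons of other genes: BLOC1S5-TXNDC5 (564 and 0 reads), HNRNPUL2-BSCL2 (0 and 374), POC1B-GALNT4 (1 and 290), RPS10-NUDT3 (33 and 495) and a second entry for PARL (203 and 0).

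The third question was what differed in SW780. In SW780 the median log2 ratio was above those of random lists for interferon response, mesenchymal and MHC class I genes (0.77, 0.55 and 0.34), of which 10 of 36, 8 of 21 and 1 of 19 passed the size rule as higher. It was below them for luminal urothelial, cholesterol and NRF2 target genes (−0.28, −0.38 and −0.36), of which 3 of 22, 1 of 24 and 0 of 24 passed as lower. VIM, which encodes the intermediate filament vimentin, had 21 reads in the shNT library and 281 in the shSCD1 library, 17.9-fold higher (11.5 to 29.3). FABP4, a fatty acid carrier and PPARG target, went from 445 to 93.3 CPM, 4.77-fold lower (4.57 to 4.98). SNX31, a sorting nexin of urothelial cells, was 7.88-fold lower (6.76 to 9.22). Of 12880 genes with at least 1 CPM, 191 were higher and 136 lower by the size rule.

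Other genes at the high end were the engulfment adaptor GULP1, 8.65-fold higher (6.64 to 11.4), the relaxin receptor RXFP1, 9.02-fold (6.40 to 13.0), and TNFSF18, a ligand of the TNF superfamily, 7.51-fold (5.61 to 10.2). TGFB2, a TGF-beta ligand, was 6.88-fold higher (5.26 to 9.11) and the transglutaminase TGM2 4.82-fold higher (4.28 to 5.43). At the low end, SPINK1, a trypsin inhibitor, was 12.3-fold lower (8.26 to 19.0), CLCA4 7.42-fold (6.33 to 8.73), and IDH1, the cytosolic isocitrate dehydrogenase, 4.67-fold (4.44 to 4.91).

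Of 36 interferon response genes, 34 were above 0 and 10 were higher by the size rule, with none lower and a median of 0.77 at percentile 100. IFITM1 was 3.77-fold higher (3.18 to 4.48), MX1 went from 228 to 557 CPM, and IFI27 from 165 to 424 CPM. Of 19 MHC class I genes, 16 were above 0 with a median of 0.34 at percentile 100. NLRC5, the transactivator of these genes, passed the size rule (3.23-fold higher, 2.61 to 4.00), and HLA-B had a log2 ratio of 0.88. In the NF-kB list the median was 0.09 at percentile 92.2, and IL32 was 2.69-fold higher (2.33 to 3.10).

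Of 21 mesenchymal genes, 8 were higher and 2 lower by the size rule, and the median was 0.55 at percentile 100. MMP2, a gelatinase, went from 102 to 292 CPM, FN1, which encodes fibronectin, from 280 to 734 CPM, and CDH2, which encodes N-cadherin, from 20.1 to 57.8 CPM. TGFBI and COL5A1 were the 2 lower ones. Of 21 YAP and TEAD targets, 17 were above 0 and the median was 0.29 at percentile 100; TGFB2, CCN2 (2.59-fold, 2.33 to 2.88), NT5E and AXL were higher and RBMS3 lower by the size rule. Of 20 basal and squamous genes, 11 were above 0 and 9 below, S100A9 and DSC2 were higher and SPRR3 lower by the size rule, and the median was 0.25 at percentile 99.9, or −0.16 at percentile 2.12 over the 6 measured in both lines. Markers of fibroblasts and endothelium, listed as other cell types, had a median of 0.47 at percentile 99.9 over 8 genes; FAP was 3.95-fold higher (3.47 to 4.50) and alone passed the size rule. In the shNT and shSCD1 libraries COL3A1 stood at 139 and 203 CPM, LUM at 35.9 and 40.0 CPM, ACTA2 at 14.9 and 29.4 CPM, PECAM1 at 2.76 and 3.91 CPM and VWF at 1.79 and 0.861 CPM, and 4 genes of this list also stand in another list. The other marker list, of blood cells, held 1 measured gene in each line, CD68, with log2 ratios of −0.44 in SW780 and −0.49 in UMUC3.

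Of 22 luminal urothelial genes, 20 were below 0 and 3 were lower by the size rule: SNX31, the transcription factor gene GRHL3 (2.67-fold lower, 2.40 to 2.98), and the uroplakin gene UPK1A (2.51-fold lower, 2.23 to 2.83). The median was −0.28 at percentile 0, with FOXA1 at −0.76 and KRT19 at −0.55. Of 24 cholesterol genes, 22 were below 0 and the median was −0.38 at percentile 0; MSMO1, a sterol oxidase, was 2.03-fold lower (1.89 to 2.18) and alone passed the size rule. Of 24 NRF2 targets, 21 were below 0 with a median of −0.36 at percentile 0, and none passed the size rule. AKR1C2, an aldo-keto reductase, was 1.97-fold lower (1.91 to 2.02). The 20 genes of fatty acid synthesis and desaturation had a median of −0.08 at percentile 10.9, and SCD alone passed the rule; FADS1 had a log2 ratio of −0.56 and FASN of −0.28.

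The cell cycle lists differed less in size. Of 35 DNA replication genes 31 were above 0, with a median of 0.15 at percentile 99.98, and of 37 genes of mitosis and G2/M 35 were above 0, with a median of 0.18 at percentile 100; none passed the size rule. The authors' deposited table for SW780 gives a GFOLD value above 0 to 3649 genes and below 0 to 3417, and at a GFOLD of at least 1 in size 193 higher and 127 lower. Gene models that share exons with others were again uncertain at both ends. They were UGT1A8 (10 and 2012 reads) and UGT1A7 (1818 and 48 reads), which share 61.7% and 40.6% of their exonic bases with other genes, KBTBD11-OT1 (883 and 0), BLOC1S5-TXNDC5 (0 and 527), ISY1-RAB43 (558 and 0), RAB4B-EGLN2 (558 and 5), ARPIN-AP3S2 (0 and 193) and an IFNAR2 entry (362 and 15), and also DUS4L-BCAP29 (114 and 864), a read-through name that is not in GENCODE 29.

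**Figure D1:**
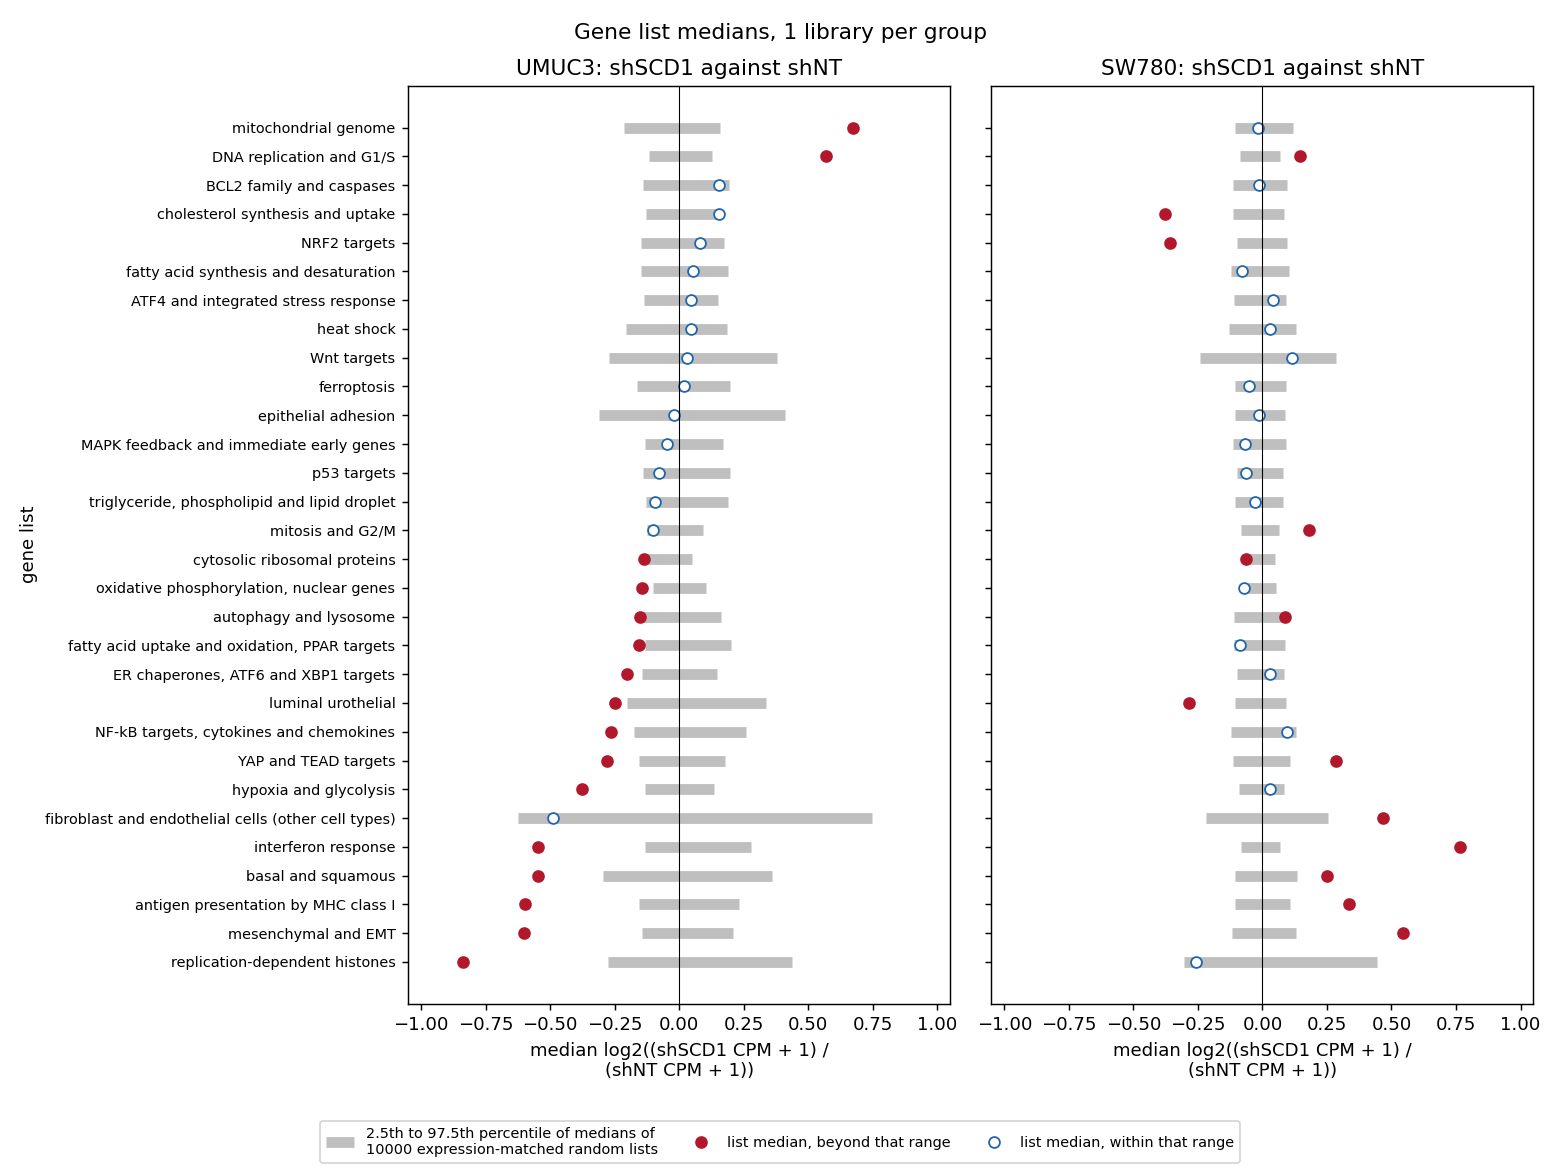
Each point is the median log2((shSCD1 CPM + 1)/(shNT CPM + 1)) of a gene list, in UMUC3 on the left and SW780 on the right. Grey bars span the central 95% of the medians of 10000 expression-matched random lists, and filled points lie beyond them. The interferon response list stands at −0.55 in UMUC3 and 0.77 in SW780, and DNA replication and G1/S at 0.57 and 0.15.

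The last question was what the lines had in common. Besides SCD, genes lower in the shSCD1 library of both lines included TGFBI, a matrix protein induced by TGF-beta, the matrix genes TNC and COL5A1, the kinase gene PLK2 and the axon guidance gene SEMA3A. TGFBI was 2.47-fold lower in UMUC3 (2.40 to 2.54) and 3.33-fold lower in SW780 (3.14 to 3.55). PLK2 was 3.98-fold (3.81 to 4.16) and 2.33-fold lower (2.26 to 2.40). TNC, which encodes tenascin C, was 2.78-fold (2.56 to 3.01) and 3.17-fold lower (2.49 to 4.07), and COL5A1 5.23-fold (4.22 to 6.53) and 2.39-fold lower (2.22 to 2.58). Across the 11152 genes measured in both lines, the log2 ratios had a Pearson correlation of 0.03 and a Spearman correlation of 0.03; genes are not independent replicates. DNA replication genes were above the random lists in both lines, and luminal and cytosolic ribosomal protein genes below them in both, although in UMUC3 the 13 measured luminal genes went both ways, with 7 below 0 and 6 above (median −0.25 at percentile 1.13). Of these KRT7 and KRT18 (2.19-fold, 2.12 to 2.27) were lower and CYP2J2 higher by the size rule, and the ribosomal list was within the random lists of UMUC3 with the trend with GC content and length removed (percentile 9.31).

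In all, 21 genes were lower in both lines by the size rule, where independent lists would share 1.27, and 4 were higher in both, where independent lists would share 2.02. SEMA3A was 3.03-fold lower in UMUC3 (2.71 to 3.40) and 2.56-fold in SW780 (2.32 to 2.83). PRICKLE1, a planar polarity gene, DSEL and RBMS3 were also lower in both, with log2 ratios of −2.80 and −1.35, −1.43 and −1.52, and −1.30 and −1.41 in UMUC3 and SW780. BEST1, a chloride channel gene, had the lowest ratios (−5.18 and −4.70), with 1589 and 31 reads in UMUC3 and 1615 and 22 in SW780; 14.2% of its exonic bases lie in exons of other genes. Of the genes higher in both, DPYSL5 had log2 ratios of 1.38 and 1.18 and GULP1 of 1.17 and 2.58. Count tests over both lines, with cell line as a block, were added after seeing the data. In them edgeR called no gene at an adjusted p of 0.05. DESeq2 called 13 of the 21 lower and 1 of the 4 higher, but not DSEL, RBMS3, DPYSL5 or GULP1 (DESeq2 adjusted p of 0.221, 0.648, 0.535 and 0.221). The 21 and 4 genes were picked because the lines went the same way, and the tests used the same libraries. Spread in the tests comes only from disagreement between the lines, so the overlap is no independent check.

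Opposite directions past the size rule were seen for 17 genes, where independent lists would give 3.36. IDH1 was 3.01-fold higher in UMUC3 (2.73 to 3.32) and 4.67-fold lower in SW780 (4.44 to 4.91). It stood at 67.1 CPM in the UMUC3 shSCD1 library and at 68.5 CPM in that of SW780. CPM is scaled over the genes deposited for each line, which differ, so these levels are not directly comparable. THBS1 was 12.3-fold lower in UMUC3 and 2.93-fold higher in SW780 (2.87 to 2.98). IL32, IFIT1, SH3RF2 and CPS1 were lower in UMUC3 and higher in SW780. Without genes that share at least 50% of their exonic bases with others or are not in GENCODE 29, 9 opposite genes and 16 genes lower in both were counted.

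**Figure D2:**
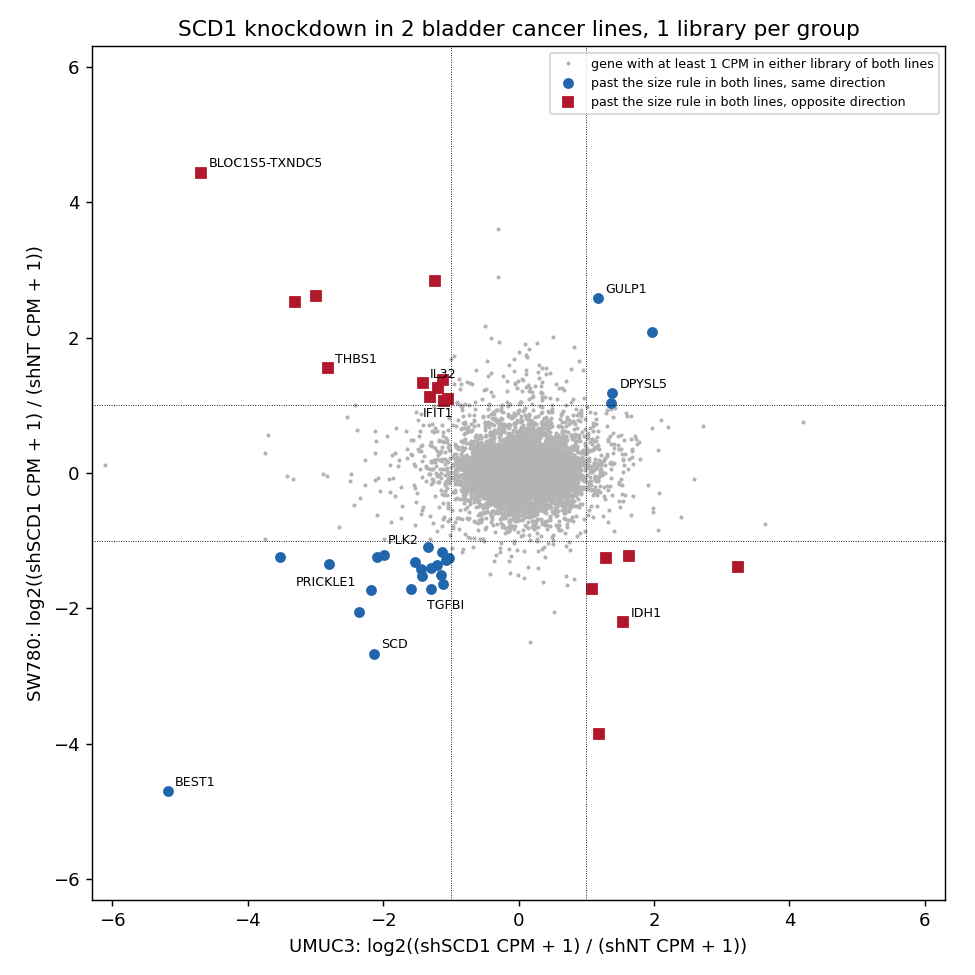
Each point is a gene measured in both lines, with its log2((shSCD1 CPM + 1)/(shNT CPM + 1)) in UMUC3 on the horizontal axis and in SW780 on the vertical axis. Dotted lines mark log2 ratios of 1 and −1. Blue circles are the 21 genes lower and 4 genes higher in both lines, and red squares are the 17 genes past the size rule in opposite directions.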

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

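The tests on GC content and length, on columns in the other order, on single libraries and on genes measured in both lines were chosen only after the result was seen; the bound for GC content and length was written before its value was seen. The differences between the lines were not tested, because each group had 1 library.

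Gene lists with medians beyond the random lists in opposite directions were taken up as differences between the lines. The UMUC3 median minus the SW780 median was −1.31 for the interferon response, −0.93 for MHC class I antigen presentation, −1.15 for mesenchymal genes, −0.80 for basal and squamous genes, −0.57 for YAP and TEAD targets, and −0.24 for autophagy and lysosome genes. Over the genes measured in both lines, 5 of these lists stayed beyond the random lists in opposite directions, but the 6 basal and squamous genes had medians of −0.55 in UMUC3 and −0.16 in SW780, both below the random lists, so its opposite directions rest on genes measured in SW780 alone. The autophagy list was within the random lists of UMUC3 at a filter of 5 CPM, at percentile 12.7. Single genes past the size rule in opposite directions were BLOC1S5-TXNDC5 (difference −9.12), IDH1 (3.75), THBS1 (−4.36), IL32 (−2.74), SH3RF2 (−2.44), IFIT1 (−2.44) and CPS1 (−2.14). BLOC1S5-TXNDC5 is a read-through model with 100% of its exonic bases in other genes.

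For these lists, GC content and transcript length were weighed first. With that trend removed within each line, 6 of the 6 lists, each over all genes measured in its line, stayed beyond the random lists in opposite directions, which speaks against it as the whole cause. Columns in the other order in 1 of the 2 tables would give SCD opposite signs, but the larger of its 2 log2 ratios was −2.13. A difference between single libraries unrelated to SCD, such as in density or handling of a culture, stays open and cannot be told apart from the knockdown with 1 library per group, and so does a response to the knockdown that differs between the lines.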

How the results depend on the processing

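No paired analysis was possible because each group held 1 library, other than the count tests over both lines, which pair the libraries by cell line. The count tests, the deposited scale, the exon-sharing filter, the GC and length trend and the list medians over genes measured in both lines were chosen after seeing the data.

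Centring subtracted 0.03 from the ratios in UMUC3 and −0.01 from those in SW780. Centred on the median, SCD went from −2.13 to −2.16 in UMUC3 and from −2.67 to −2.66 in SW780. Genes higher and lower in UMUC3 went from 347 and 306 to 318 and 321 with the median, and to 316 and 322 with the trimmed mean. Counts of higher and lower genes moved over 1.5 times as follows. With a pseudocount of 0.1 they were 717 and 518 in UMUC3, 372 and 228 in SW780, with 27 higher, 33 lower and 35 opposite in both lines. At a log2 ratio of 0.5 they were 1867 and 1265, 857 and 673, and 124, 84 and 169. By the authors' GFOLD they were 3826 and 6042, 3649 and 3417, and 849, 1299 and 2019. On the deposited scale, where genes with a single read are counted, they were 5032 and 3767, 1254 and 1136, and 214, 161 and 365. At 5 CPM, 222 were higher in UMUC3 and 8 opposite; without exon-sharing genes 9 were opposite. The causes of the other shifts were not tested.

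With cell line as block, edgeR called 0 genes higher and 0 lower at an adjusted p of 0.05, with 418 of 13554 tested genes at an unadjusted p below 0.05, where 678 would be expected with no change, and DESeq2 called 7 higher and 20 lower, of which 1 and 13 were among the 4 and 21. SCD had an adjusted p of 0.722 in edgeR and 1.20e-23 in DESeq2. Spread in both tests comes only from disagreement between the lines and not from replicate cultures. The overlap with the 4 and 21 genes, picked for agreement between the lines, is therefore no independent check. SCD was −2.23 by the authors' log2 fold change in UMUC3 and −2.61 by their GFOLD in SW780. The correlation between the lines was 0.0058 with a pseudocount of 0.1.

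Of 1692 values of 282 other named gene results, 190 moved by more than their counting error and 0 reversed; of 296 list medians, 1 left the 95% interval of its median over the list's genes, which is wide for short lists, and 1 reversed: basal and squamous genes in SW780 went from 0.25 to −0.16 (percentile 2.12) over the 6 genes measured in both lines. Ribosomal proteins (percentile 9.31) and fatty acid oxidation (3.09) in UMUC3 changed their side of the percentiles with the GC and length trend removed. Autophagy in UMUC3 did so at 5 CPM, and 6 lists within the random range left it. In UMUC3 the latter were mitosis (percentile 1.02), MAPK feedback and immediate early genes (0.31 at 5 CPM, 2.35 over genes measured in both lines) and Wnt targets (99.9 and 98.3). In SW780 they were fatty acid oxidation (0.76), oxidative phosphorylation (1.04) and histones (2.22 over genes measured in both lines). Ratios of genes near 1 CPM are limited by depth.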

Other observations

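The tests on GC content and length, on exon sharing, on genes that vary between any 2 libraries and on genes measured in both lines were chosen only after the result was seen; the test on RNA without a poly(A) tail was written before, but the rule by which it decides nothing was added after its value was seen.

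Further lists had the following medians. The 58 measured cytosolic ribosomal protein genes had medians of −0.14 in UMUC3 (percentile 1.58, or 9.31 with the trend with GC content and length removed) and −0.06 in SW780 (percentile 1.72), and the 49 nuclear genes of oxidative phosphorylation −0.15 (percentile 0.31) and −0.07 (percentile 4.33, or 1.04 with that trend removed), beside the higher transcripts of the mitochondrial genome in UMUC3; in SW780 these 13 transcripts had a median of −0.02 (percentile 41.5). ER chaperones in SW780 had a median of 0.03 (percentile 82.5) and hypoxia and glycolysis genes 0.03 (percentile 81.6). Medians in UMUC3 and SW780 were 0.05 and 0.04 for the ATF4 list, 0.02 and −0.05 for ferroptosis, and 0.05 and 0.03 for heat shock. For p53 targets they were −0.08 and −0.06, and for the BCL2 family and caspases 0.15 and −0.01. For MAPK feedback and immediate early genes they were −0.05 and −0.07, and for Wnt targets 0.03 and 0.11. They were −0.02 and −0.01 for epithelial adhesion, and −0.09 and −0.03 for triglyceride and lipid droplet genes. The medians given from ER chaperones in SW780 to this point were all within the random lists. With at least 5 CPM, however, Wnt targets in UMUC3 had a median of 0.77 (percentile 99.9), beyond them. MAPK feedback and immediate early genes then had one of −0.21 (percentile 0.31), also beyond them. Over genes measured in both lines these medians were 0.40 and −0.15 (percentiles 98.3 and 2.35). Before that filter the Wnt list held only 9 genes in UMUC3, 5 above 0 and 4 below. The filter left out AXIN2 (−0.52) and TCF7 (0.03). Of the Wnt genes kept, LEF1, ZNRF3, NKD2 and NKD1 were above 0 (0.77 to 1.68). DKK1 (−1.90), DKK3 (−0.87) and CTNNB1 (−0.03) were below it. The MAPK list held 26 genes before the filter, 13 above 0 and 13 below. Those above included DUSP4 (0.96) and SPRY4 (0.71), and those below DUSP5 (−0.96) and MYC (−0.61). NRF2 targets in UMUC3 had a median of 0.08 (percentile 81.3), autophagy genes −0.15 in UMUC3 (−0.08 at percentile 12.7 with at least 5 CPM) and 0.09 in SW780, fatty acid oxidation genes in SW780 −0.09 (percentile 7.08, or 0.76 with that trend removed), and the 3 fibroblast and endothelial markers measured in UMUC3 −0.49 (percentile 5.76).

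Within these lists single genes stood apart. DDIT3, which encodes the stress factor CHOP, was 3.69-fold lower in the UMUC3 shSCD1 library (3.44 to 3.97) while ASNS, another ATF4 target, had a log2 ratio of 0.87. The Wnt antagonist gene DKK1 was 3.87-fold lower in UMUC3 (3.53 to 4.24) and NKD1 4.68-fold higher (3.25 to 6.93). CLDN1, a tight junction gene, was 2.43-fold higher in UMUC3 (2.29 to 2.58) and 1.27-fold lower in SW780 (1.24 to 1.30). DUSP1, a phosphatase of MAP kinases, had log2 ratios of −1.01 in UMUC3 and −0.92 in SW780.

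The number of genes lower in both lines, 21 against 1.27 for independent lists, was weighed. Removal of the trend with GC content and length left 21 genes, and removal of exon-sharing genes left 16, so neither accounts for the whole. Genes that vary between any 2 libraries stay open: if they raised every combination of directions alike, the largest excess among the other 3, 5.12-fold, would give 6.51 genes, below the lower 95% Poisson limit of 13.0 for a count of 21, but that limit takes genes as independent, the 21 include SCD, and 1 library per group does not show how genes move together. A response to SCD1 loss common to both lines is a hypothesis that these counts leave open, and so are effects of the hairpin on other transcripts, which may act alike in both lines and were not tested, since hairpin sequences were not used here.

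All 8 measured genes of the histone list were below 0 in UMUC3, with a median of −0.84 (percentile 0.01) and H2AC6 4.02-fold lower (3.49 to 4.63), while DNA replication genes were higher; in SW780, 6 histone genes had a median of −0.26 (percentile 3.96, or 2.22 among genes measured in both lines). With the trend with GC content and length removed, the UMUC3 histone median was −0.81, which speaks against that trend as the whole cause. Histone messages lack a poly(A) tail, so carry-over of such RNA that differed between the libraries could lower them. Other RNAs without a tail had a median of −0.012, above the bound of −0.2 set beforehand as evidence against carry-over. That bound was met, but after the value was seen it was judged to decide nothing, because only 7 genes were measured and they went both ways (RN7SL2 −2.17, RN7SL1 −1.64 and RN7SL4P −0.69, and 4 small nucleolar RNAs near 0), so carry-over stays open.

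Genes with at least 5 CPM in 1 library and 3 reads or fewer in the other of the same line numbered 13 in UMUC3 and 7 in SW780. Of those in GENCODE 29, 8 of 9 and 5 of 5 share at least 50% of their exonic bases with other genes, as do 3.88% and 3.79% of the remaining genes, and INHBA is the exception.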
